A study of Hippocampus with 4 samples.

How the data were processed

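The material was RNA from HT-22 cells, an immortalised mouse hippocampal neuronal line, prepared with TRIzol, per the labels' protocols. The series holds 4 libraries, 1 per group: control cells, cells given 5 mM glutamate for 24 h, cells given the same glutamate with 100 µg/mL of a Passiflora edulis (passion fruit) pulp extract, and cells given it with 25 µg/mL of a peel extract. The control is labelled both as vehicle and as untreated, without a time, so whether these cells received vehicle is not known. Groups and doses were taken from the labels. Nothing in the labels pairs the libraries, and no library was left out.

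The authors deposited 3 tables, each setting the glutamate library against 1 of the others, with 14247, 14247 and 14220 genes for control, pulp extract and peel extract. Per the file headers, each table gives an expression value per library, a log2 ratio, a p-value, a false discovery rate, a call and the gene length. Bowtie2 and RSEM are named without versions in the submitters' processing notes, and the genome build is not given in the sources used here. The expression values deposited by the authors are FPKM (fragments per kilobase of gene length, scaled to library size), written with 2 decimals and with 0 replaced by 0.01. FPKM was identified from the values, since the file headers name no unit. The log2 ratios deposited by the authors are those of the paired FPKM values. The p-values deposited by the authors come from a Poisson comparison of the reads of 2 libraries, which compares those libraries and not the conditions.

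A spreadsheet had turned 34.8%, 34.5% and 34.6% of the expression cells of the 3 tables into dates. These were decoded back to numbers, after which 0 of the gene pairs differed by more than 1e-06 from the deposited log2 ratio. The tables listed 14892 genes together, 13755 of them in all 3. A gene that a table left out was taken as listed at 0 in that table's own library; in every such case the glutamate value in the other tables was at most 0.01. Gene symbols and identifiers are those of the tables. The 14 genes whose symbols had become dates were not named, and 4 entries shared a symbol with another and entered no gene list.

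The analysis had been laid out for read counts. Because the tables hold FPKM, the ratio fixed beforehand for such a unit was used: log2 of (FPKM + 0.5) in one library over (FPKM + 0.5) in the other, without further scaling, which understates the change of low genes. A gene was measured in a comparison if it reached 1 FPKM in the higher library, and was called different if its log2 ratio was at least 1 in size. This call is a rule of size, not a test. There are no replicates, so no difference has a replicate check and no p-value across genes is given.

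Whole reads per gene were recovered from the deposited p-values, since only certain pairs of whole reads give a printed p-value and both FPKM values. Pairs had to match the p-value within a relative 8e-06, and genes above about 10000 reads were estimated from FPKM and length. Reads were recovered for 94.9%, 95.0%, 94.9% and 94.9% of genes in the control, glutamate, pulp and peel libraries. These shares include genes that a table left out, which were taken as 0 reads without a p-value. The remaining genes, among them the most abundant, held 28.5%, 28.1%, 27.4% and 27.4% of the reads in the same order. Of 12385 genes whose glutamate reads came from at least 2 tables separately, 12370 (99.9%) had the same number each time. With the estimated reads included, reads in genes came to 15690925, 15731973, 15942703 and 14226446 in the same order, so these totals are not exact counts. From these reads each ratio has a 95% exact (Clopper-Pearson) interval, called the counting interval below. It covers counting error only, not the spread between cultures, and a ratio is called beyond counting error where it excludes no difference. The interval is that of the ratio without the pseudocount, so it can lie off centre for low genes.

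The comparisons were glutamate against control, each extract against glutamate alone, and peel against pulp. For peel against pulp the values come from separate tables of the same deposited unit, and the glutamate FPKM were identical in all 3 tables. Altogether 34 gene lists were fixed before the data were examined and examined in 4 comparisons, 136 in all. Each list of at least 5 measured genes was described by its median log2 ratio and by how many of 10000 random lists of the same size, matched on mean FPKM in 20 bins, had a lower median. Lists share some genes, and this rank describes these libraries only.

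Genes were named by a rule fixed before the data were examined. It took the 10 highest and 10 lowest called genes with at least 5 FPKM in the higher library (5 and 5 for peel against pulp) and up to 4 members per list with the largest ratios. It also took Slc7a11, Hmox1, Chac1, Ddit3, Gpx4 and Nqo1 always, and 5 genes per direction and extract for the return toward control. Genes without a common symbol were not named. Histones, Entpd4, Tmem254c, Eif3j1, ferritins, metallothioneins and ribosomal protein genes have near-identical copies or pseudogenes, and their values are uncertain because reads can be divided among the copies.

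The comparisons that share the glutamate library were set beside 100 simulations of unchanged libraries with counting error alone, and with a spread between libraries of 0.0400 (estimated from peel against pulp), 0.1 or 0.2. The spreads of 0.0400 and 0.2, and a simulation with the extract libraries drawn at the glutamate level, were added after the first values had been seen. The recovered glutamate reads were also divided at random into equal independent parts, 1 per comparison, 100 times.

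The procedures were tested on simulated data. Of simulated genes, 74.0%, 74.4% and 74.9% for the control, pulp and peel tables had a single read pair, which was right in 100% of cases. With 50 genes changed per fold size, 2-fold changes were called in 28%, 28%, 40% and 32% for glutamate against control, pulp and peel against glutamate, and peel against pulp. For 3-fold changes the shares were 94%, 100%, 96% and 92%, and for 1.5-fold changes 0% in each. False calls were 3 of 10101, 2 of 10112, 1 of 10106 and 0 of 10069 unchanged genes. The libraries of this test were drawn with counting error alone, so its shares leave out the spread between cultures. In the unchanged libraries simulated with a spread of 0.1, pulp against glutamate had 2.46 higher and 2.32 lower calls on average. With a spread of 0.2 there were 74.31 and 72.71. In glutamate against control, 95.1% of the intervals held the true ratio and 95 of 100 unchanged lists lay in the middle 95% of random lists.

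Alternatives fixed beforehand were scaling by FPKM totals or median-of-ratios factors, no minimum level or 5 FPKM, a pseudocount of 1 FPKM, intervals widened by an assumed coefficient of variation of 0.4, the authors' deposited calls, and the divided glutamate reads. Recovered reads with TMM factors, and leaving out genes listed at 0, were added after the data were seen. Computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots used matplotlib 3.10.9.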

Results

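HT-22 cells are an immortalised mouse hippocampal line that is widely used to study glutamate toxicity. High extracellular glutamate blocks cystine uptake in these cells, which lowers glutathione and leads to oxidative stress. Gene expression was measured by RNA sequencing in 4 libraries: control (vehicle or untreated), 5 mM glutamate for 24 h, glutamate with 100 µg/mL pulp extract, and glutamate with 25 µg/mL peel extract of Passiflora edulis. The libraries held 15690925, 15731973, 15942703 and 14226446 recovered or estimated reads in genes. In the same order, 10266, 10343, 10266 and 10258 genes reached 1 FPKM. Each group was a single library, so no difference below has a replicate check, and the 95% counting intervals given as ranges cover counting error only. "Higher" and "lower" therefore compare libraries, and ratios are log2 ratios with a pseudocount of 0.5 FPKM.

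The comparison of glutamate with control asked what glutamate changed. Targets of Atf4, the transcription factor of the integrated stress response, were higher with glutamate. Ddit3 (gene identifier 13198), which encodes the stress-induced factor CHOP, was at 154 FPKM with glutamate and 52.99 FPKM in control, a ratio of 1.53 (1.42 to 1.68). Chac1 (69065), an enzyme that degrades glutathione, was at 101 against 35.4 FPKM, 2.85-fold on the FPKM scale (2.63 to 3.08). Trib3 (228775), a pseudokinase induced under stress, had a ratio of 1.45 (1.34 to 1.60), and the hormone gene Fgf21 (56636) one of 1.51 (1.03 to 3.87) at 2.15 FPKM. Of 33 measured members of this list, 25 were higher and 2 lower beyond counting error, and 5 were called. The list's median of 0.33 lay above 10000 of 10000 random lists of matched level.

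Among single genes outside that list, Gadd45a (13197), a growth arrest and DNA damage gene, was at 42.3 FPKM with glutamate and 12.9 FPKM in control, a ratio of 1.67 (1.49 to 1.92). Txnip (56338), which encodes an inhibitor of thioredoxin, was at 43.5 against 13.4 FPKM, a ratio of 1.66 (1.56 to 1.83). Its relative Arrdc3 (105171) had a ratio of 1.09 (0.97 to 1.40). Ero1l (50527), an oxidase of the endoplasmic reticulum, had a ratio of 1.19 (1.13 to 1.26), and the metallothionein Mt2 (17750) one of 1.16 (0.97 to 1.37). The lowest gene by the naming rule was the histone gene Hist1h3b (319150), at 3.22 against 8.77 FPKM, a ratio of -1.32 (-2.28 to -0.70).

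Nrf2 targets, the antioxidant and detoxification genes controlled by that factor, were also higher with glutamate. Hmox1 (15368), the haem-degrading enzyme, was at 116 FPKM against 47.6 FPKM, a ratio of 1.28 (1.18 to 1.38). The quinone reductase gene Nqo1 (18104) had a ratio of 0.89 (0.78 to 1.02), and the ferritin heavy chain gene Fth1 (14319) one of 0.77 (0.75 to 0.79). Of 27 measured members, 20 were higher and 1 lower beyond counting error, and 1 (Hmox1) was called. Their median of 0.26 lay above 10000 of 10000 random lists. The cystine transporter gene Slc7a11 (26570) was at 5.41 against 4.55 FPKM, a ratio of 0.23 (0.10 to 0.40). Gpx4 (625249), which reduces lipid peroxides, was at 465 against 445 FPKM, a ratio of 0.06 (0.01 to 0.11).

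Genes of glycolysis and hypoxia were higher as a group, with 20 of 25 measured members higher and 0 lower beyond counting error and a median of 0.41. Called members were Ndrg1 (17988) at 1.08 (1.01 to 1.17), the growth factor gene Vegfa (22339) at 1.01 (0.93 to 1.08) and the mitophagy receptor gene Bnip3 (12176), at 139 against 67.6 FPKM, a ratio of 1.04. Immediate early genes, which respond within minutes to growth signals, had a median of 0.46, with 14 of 23 members higher, 0 lower and 0 called. Egr1 (13653) had a ratio of 0.97 (0.85 to 1.15) and Myc (17869) one of 0.78 (0.71 to 0.85). NF-kB and inflammatory genes had a median of 0.29 and 8 of 17 members higher, with Tnfaip3, a feedback inhibitor of that pathway, at 0.72 (0.57 to 1.03). All 3 medians lay above 10000 of 10000 random lists. Autophagy, mitophagy and lysosome genes had a smaller median of 0.11, above 9999 of 10000, with 14 of 32 members higher. The p53 targets had a median of 0.12, above 9937, with 7 of 19 higher, and the 5 measured metallothionein and metal transport genes a median of 0.23, above 9901.

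Cholesterol biosynthesis genes were lower with glutamate. Of 24 measured members, 19 were lower and 0 higher beyond counting error, with a median of -0.31 that lay above 0 of 10000 random lists. Hmgcs1 (208715), an early enzyme of the pathway, was at 93.3 against 133 FPKM, a ratio of -0.51 (-0.57 to -0.46), and Insig1, a sterol sensor, had one of -0.41 (-0.48 to -0.34). Endoplasmic reticulum chaperone genes had a median of -0.18, above 0 of 10000 random lists, with 13 of 19 members lower. Within that list Herpud1, which takes part in the degradation of misfolded proteins, went the other way at 0.65 (0.54 to 0.76). Heat shock genes had a median of -0.13, above 3 of 10000, with 11 of 17 lower, among them the constitutive chaperone gene Hspa8 at -0.26 (-0.28 to -0.24). Proteasome subunit genes had a median of -0.10, above 64 of 10000, with 18 of 26 lower.

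Of 10394 genes measured with glutamate and in control, 32 were called higher and 8 lower, and 1966 and 1545 were higher and lower beyond counting error. The authors' deposited table calls 43 higher and 6 lower. Of the 40 called genes 6 were histone genes and 5 were listed at 0 in a library, and with a minimum of 5 FPKM the counts were 17 and 1. With no minimum 13 were lower. With a pseudocount of 1 FPKM they were 20 and 3, and with an assumed coefficient of variation of 0.4 they were 11 and 2. With recovered reads, where scaling, pseudocount, minimum and call rule changed too, they were 103 and 17. With that coefficient of variation Gadd45a, Txnip and Fgf21 were called, but Ddit3, Chac1, Trib3, Hmox1, Ero1l, Mt2, Arrdc3, Ndrg1, Vegfa, Bnip3 and Hist1h3b were not. The widened interval is that of the ratio without the pseudocount, which is larger for low genes such as Fgf21, at 2.15 against 0.43 FPKM. It does not make Fgf21 firmer than Ddit3. Vegfa was not called either with FPKM totals (0.996), median-of-ratios factors (0.98), a pseudocount of 1 FPKM or recovered reads (0.98).

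**Figure D1:**
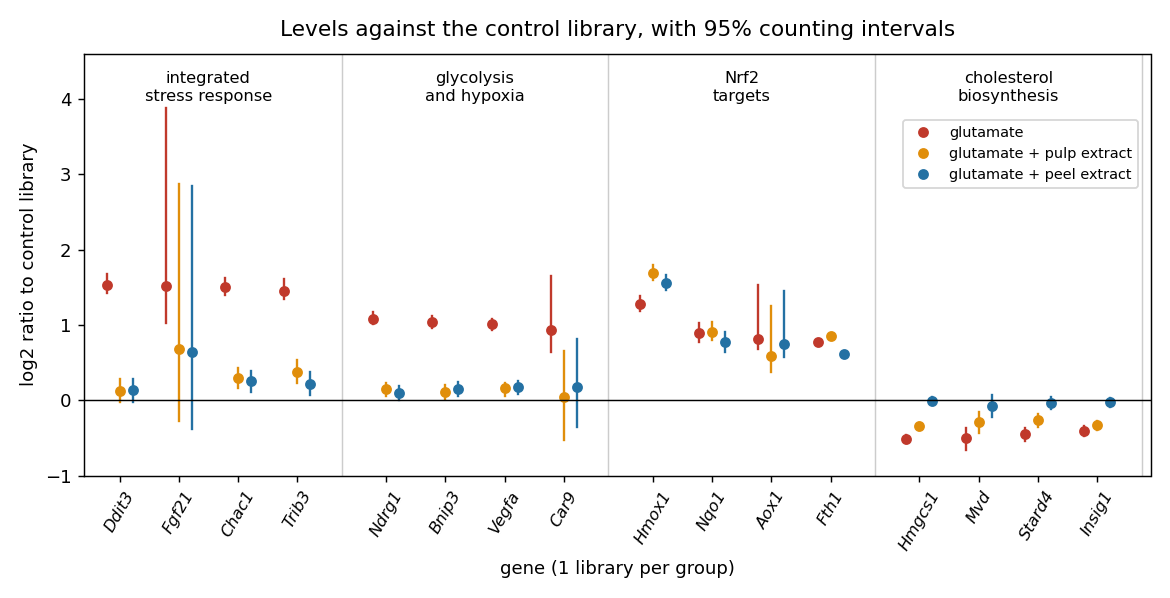
Log2 ratios to the control library of named genes in the glutamate, pulp extract and peel extract libraries, 1 library per group, with 95% counting intervals as bars, which are those of the ratio without the pseudocount. Ddit3 was at 1.53 with glutamate alone, whereas Hmox1 was at 1.28 with glutamate alone, 1.68 with pulp and 1.55 with peel extract.

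The comparison of pulp extract with glutamate alone asked what the extract changed in glutamate-treated cells. The stress genes that were highest with glutamate were lower with pulp extract. Gadd45a was at 14.6 FPKM against 42.3 FPKM, 0.346 times the level on the FPKM scale (0.301 to 0.398), and Ddit3 at 57.8 against 154 FPKM, a ratio of -1.40 (-1.55 to -1.30). Egr1 had a ratio of -1.23 (-1.43 to -1.11), Chac1 of -1.20 (-1.31 to -1.10), Trib3 of -1.08 (-1.21 to -0.97) and Tcim (69068) of -1.02 (-1.32 to -0.81). Hmox1 did not follow them: it was at 154 FPKM with pulp extract and 116 FPKM with glutamate alone, a ratio of 0.41 (0.34 to 0.48). For Nqo1 the ratio was 0.02 (-0.08 to 0.12), for Slc7a11 -0.07 (-0.22 to 0.07) and for Gpx4 -0.14 (-0.18 to -0.08).

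Of the Atf4 targets, 21 of 33 were lower and 4 higher with pulp extract beyond counting error, and their median was -0.20. Immediate early genes had a median of -0.47, with 15 of 23 lower, and glycolysis and hypoxia genes one of -0.36, with 22 of 25 lower. These 3 medians lay above 0 of 10000 random lists, as did that of the ribosomal protein genes, -0.09 with 63 of 81 lower. NF-kB and inflammatory genes had a median of -0.18, above 1 of 10000, and metallothionein and metal transport genes one of -0.32, above 7. Heat shock genes were higher, with a median of 0.12 above 9999 of 10000 and 11 of 17 members higher. Endoplasmic reticulum chaperone genes had a median of 0.07, above 9848. The Nrf2 target median was 0.05, above 9815, with 10 of 27 members higher and 4 lower; Txnrd1, a thioredoxin reductase gene, stood at 0.31 (0.26 to 0.37). The cholesterol biosynthesis median was 0.01, above 4999.

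Of 10394 measured genes, 5 were called higher and 22 lower with pulp extract, and 1707 and 1532 were higher and lower beyond counting error. The authors' deposited table calls 3 higher and 31 lower. The genes called higher, named after their values were seen where the rule did not name them, were Hist1h4n, Hist2h2aa2, Hist1h2be, Htd2 and Fcgr4. Hist1h4n was listed at 0 with glutamate and at 5.36 FPKM with pulp extract, whereas its near-identical copy Hist1h4m was at 6.64 FPKM and then listed at 0. Without genes listed at 0 there were 2 called higher, and with no minimum level 9. With a minimum of 5 FPKM the counts were 1 and 7, with the assumed coefficient of variation 8 were lower, and with recovered reads they were 11 and 92. With that coefficient of variation Gadd45a, Ddit3, Egr1, Chac1, Trib3 and Tcim were not called, and Tcim was not called either with FPKM totals or a pseudocount of 1 FPKM (-0.99 with each).

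The comparison of peel extract with glutamate alone asked the same of the other extract. Gadd45a was at 14.3 FPKM with peel extract against 42.3 FPKM, a ratio of -1.53 (-1.78 to -1.36), and Ddit3 at 58.3 against 154 FPKM, a ratio of -1.39 (-1.55 to -1.29). Chac1 had a ratio of -1.24 (-1.37 to -1.14), Trib3 of -1.24 (-1.38 to -1.13) and Egr1 of -1.03 (-1.23 to -0.91). Mt2 was at -1.01 (-1.23 to -0.83) and Txnip at -1.01 (-1.14 to -0.91). Hmox1 was again higher, at 141 FPKM and a ratio of 0.28 (0.20 to 0.35). Nqo1 had a ratio of -0.12 (-0.23 to -0.02), Slc7a11 of -0.07 (-0.22 to 0.08) and Gpx4 of -0.17 (-0.22 to -0.12).

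Cholesterol biosynthesis genes were higher with peel extract than with glutamate alone, 21 of 24 beyond counting error and 1 lower, with a median of 0.26 above 10000 of 10000 random lists. Hmgcs1 was at 133 FPKM against 93.3 FPKM, a ratio of 0.51 (0.46 to 0.56), and the isomerase gene Idi1 had one of 0.48 (0.42 to 0.54). Fatty acid synthesis genes had a median of 0.14, above 9986, with 11 of 13 members higher, among them the desaturase gene Scd2 at 0.31 (0.29 to 0.34). Heat shock genes had a median of 0.16, above 10000, endoplasmic reticulum chaperones 0.10, above 9971, mitosis genes 0.09, above 9970, and interferon-stimulated genes 0.10, above 9863. Lower medians were those of immediate early genes (-0.52), glycolysis and hypoxia genes (-0.45) and ribosomal protein genes (-0.15, 68 of 81 lower), each above 0 of 10000. The Atf4 target median was -0.14, above 1, with 19 of 33 lower, that of NF-kB and inflammatory genes -0.17, above 26, and that of metallothioneins and metal transport -0.20, above 205. The Nrf2 target median was -0.05, above 1643, and turned positive with scaling by FPKM totals.

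Of 10392 measured genes, 0 were called higher and 26 lower with peel extract, and 1825 and 1877 were higher and lower beyond counting error. The authors' deposited table calls 4 higher and 21 lower. With no minimum level 5 were higher. With a minimum of 5 FPKM, and likewise with the assumed coefficient of variation, 7 were lower, with a pseudocount of 1 FPKM 12, and with recovered reads 16 were higher and 108 lower. With that coefficient of variation Gadd45a, Ddit3, Chac1, Trib3, Egr1, Mt2 and Txnip were not called. With FPKM totals the calls of Egr1 (-0.98), Mt2 (-0.96) and Txnip (-0.95) ended, and that of Txnip also with median-of-ratios factors and a pseudocount of 1 FPKM (-0.99 with each).

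Peel and pulp extract were compared directly, although their doses differed (25 and 100 µg/mL), so a difference belongs to the pair of extract and dose. Lipid synthesis genes were higher with peel extract. Of 24 cholesterol biosynthesis genes 21 were higher and 0 lower beyond counting error, with a median of 0.26, and of 13 fatty acid synthesis genes 10 were higher and 1 lower, with a median of 0.22. Both medians lay above 10000 of 10000 random lists. Idi1 had a ratio of 0.42 (0.36 to 0.47), the sterol dehydrogenase gene Nsdhl of 0.39 (0.32 to 0.46), Scd2 of 0.42 (0.40 to 0.45) and the fatty acid ligase gene Acsl3 of 0.40 (0.30 to 0.52). The Nrf2 target median was -0.07, above 58 of 10000, but 16 of 27 members lay within counting error, with 10 lower, 1 higher and 0 called. Fth1 was at -0.24 (-0.26 to -0.22), Hmox1 at -0.13 (-0.20 to -0.07) and Nqo1 at -0.14 (-0.25 to -0.04). Ribosomal protein genes had a median of -0.03, above 178, with 39 of 81 lower.

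Of 32 Atf4 targets, 23 lay within counting error between the extracts, 6 were higher and 3 lower with peel extract, and 0 were called. Their median was 0.03, above 9581 of 10000. Ddit3 had a ratio of 0.01 (-0.15 to 0.16) and Chac1 of -0.04 (-0.18 to 0.08), whereas Cth was at 0.22 (0.06 to 0.37), Nupr1 at 0.21 (0.01 to 0.40) and Trib3 at -0.16 (-0.31 to -0.02). Slc7a11, also in that list, had a ratio of 0.00 (-0.15 to 0.15), and Gpx4, which is not, one of -0.03 (-0.09 to 0.02). Of 10345 measured genes, 7 were called higher and 7 lower with peel than with pulp extract, and 1053 and 1202 were higher and lower beyond counting error. Of the 14 called genes 5 were histone genes and 5 were listed at 0 in a library, and Hist1h4n, at 0.84 against 5.36 FPKM, was the only called gene with at least 5 FPKM. The counts were 4 and 4 with a pseudocount of 1 FPKM, 0 and 1 with a minimum of 5 FPKM, and 30 and 28 with recovered reads. With no minimum level 12 were lower, with the assumed coefficient of variation 4 were higher, and without genes listed at 0 there were 3 higher. Above 20 FPKM on average, the log2 ratios had a standard deviation across genes of 0.10 for peel against pulp and of 0.17, 0.15 and 0.17 for the other comparisons.

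The return toward control was examined for genes called with glutamate. The binomial intervals of shares treat genes as independent, which they are not, and cover no spread between cultures. Of the 32 genes higher with glutamate, 10 were called lower with pulp extract (31.2%, exact binomial interval 16.1% to 50.01%) and 13 with peel extract (40.6%, 23.7% to 59.4%). The 5 with the largest glutamate ratios were Gadd45a, Tmem254c, Entpd4, Ddit3 and Chac1 for pulp, and Gadd45a, Txnip, Entpd4, Ddit3 and Chac1 for peel extract. Against control, Gadd45a stood at 0.17 with pulp and 0.14 with peel extract, Ddit3 at 0.12 and 0.14, Chac1 at 0.30 and 0.25, and Txnip at 0.82 and 0.65. Median ratios of the 32 genes were 1.18 for glutamate against control, and 0.29 with pulp and 0.20 with peel extract against control. Of the 8 genes lower with glutamate, 2 were called higher with pulp extract, Hist2h2aa2 and Hist1h2be, and 0 with peel extract. The order of the extracts depended on the setting. For genes higher with glutamate, the shares for pulp and peel extract were 44.2% and 30.2% with the calls of the authors' deposited table, 35% and 30% with a pseudocount of 1 FPKM, 36.4% and 18.2% with the assumed coefficient of variation, and 38.8% and 37.9% with recovered reads. For genes lower with glutamate, the authors' calls gave 16.7% for either extract. Among 556 genes higher with glutamate at a false discovery rate of at most 0.001 in the authors' deposited table, with a median ratio of 0.36, 1.8% and 2.34% were called lower with pulp and peel extract, and 436 and 439 were lower beyond counting error. Among 456 genes lower with glutamate at that rate, with a median ratio of -0.21, 1 was called higher with pulp and 0 with peel extract, and 327 (71.7%) and 366 (80.3%) were higher beyond counting error. Most genes of either set changed too little with glutamate to be called back even on full return. Both sets were picked and then compared with the same glutamate library, and no unchanged value was simulated for them. Entpd4, Tmem254c and these histone genes have near-identical copies and are uncertain.

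In the Nrf2 target list the median against control was 0.26 with glutamate, 0.35 with pulp and 0.29 with peel extract, and Hmox1 stood at 1.68 (1.60 to 1.79) and 1.55 (1.46 to 1.66) with the extracts. In the Atf4 target list the same medians were 0.33, 0.10 and 0.13, and in the cholesterol biosynthesis list -0.31, -0.31 and -0.02.

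Part of any return is built in, because the same glutamate library enters every comparison. In simulated unchanged libraries with counting error alone, 16.9% and 14.4% of genes called higher with glutamate were called lower with pulp and peel extract, but only 1.6 genes were called higher on average, beside the observed 32. With the extract libraries drawn at the level of the glutamate library, which keeps the 32 genes and takes that library's counting error as real, the shares were 0.03125% and 0.0625%. With the glutamate reads divided into independent parts, 37.63 genes were called higher on average and the shares were 23.8% and 23.4%. Each part holds fewer reads, so the lower shares can also come from lost depth and do not measure the built-in part. The covariance across 10290 genes between glutamate over control and extract over glutamate was -0.0258 for pulp and -0.0270 for peel extract (r = -0.66 and -0.67, Spearman -0.63 and -0.64). Genes are not independent replicates. The simulated covariances of unchanged libraries were -0.00565 and -0.00564 with counting error alone (r = -0.50 and -0.49), and -0.0244 for either extract with a spread of 0.1 between libraries (r = -0.50 for each). The simulated r stay near -0.50 at any spread, because all libraries were given the same one. The spread of 0.1 gave a covariance near the observed one, but 2.51 genes called higher with glutamate on average. Of these, 15.1% and 13.9% were called lower with pulp and peel extract.

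Lower calls were shared by the extracts for 9 genes and higher calls for 0. Of the shared genes, Gadd45a, Ddit3, Egr1, Chac1, Trib3 and Entpd4 came under the naming rule, and Tnnc1, Gpr35 and Hist1h2ad were named after their values were seen. Independent lists of these sizes among 10366 genes would share 0.055. Unchanged libraries simulated against the same glutamate library shared 0.23 on average with counting error alone, 0.17 with a spread of 0.0400, 0.41 with 0.1 and 5.88 with 0.2. The simulated shared higher calls were 0.22, 0.31, 0.36 and 13.18 at these 4 settings. The spread of 0.2 also gave 74.31 higher and 72.71 lower calls for pulp, and 73.59 and 74.88 for peel extract, far more than observed. With divided glutamate reads, 7.25 were shared on average. No minimum level, and likewise recovered reads, gave 2 shared higher calls. The number of shared lower calls was 8 with FPKM totals, where Egr1 was not called with peel extract, 5 with a minimum of 5 FPKM, 2 (Entpd4 and Gpr35) with the assumed coefficient of variation and 43 with recovered reads. Entpd4 and Gpr35 are low genes, at 1.03 and 1.06 FPKM with glutamate, which the widened interval favours. Across 10290 genes the pulp and peel ratios had r = 0.70 (Spearman 0.67) and a covariance of 0.0268. Unchanged libraries gave r of 0.49, 0.49, 0.50 and 0.50 at the same 4 settings, and covariances of 0.00563, 0.00866, 0.0244 and 0.0810. All simulated libraries had the same spread, which alone puts r near 0.50 at any spread. An observed r above that cannot separate an effect from a glutamate library that deviates more than the others. With the glutamate reads divided into independent parts, 1 per extract, r was 0.48 and the covariance 0.0212 on average. Dividing removes the shared counting error, but r also falls because each part holds fewer reads. The simulated libraries share the glutamate library as well, so sharing among equally variable libraries is already in their values. A deviation of the single glutamate library could give part or all of the observed r and covariance, and these simulations do not bound it.

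**Figure D2:**
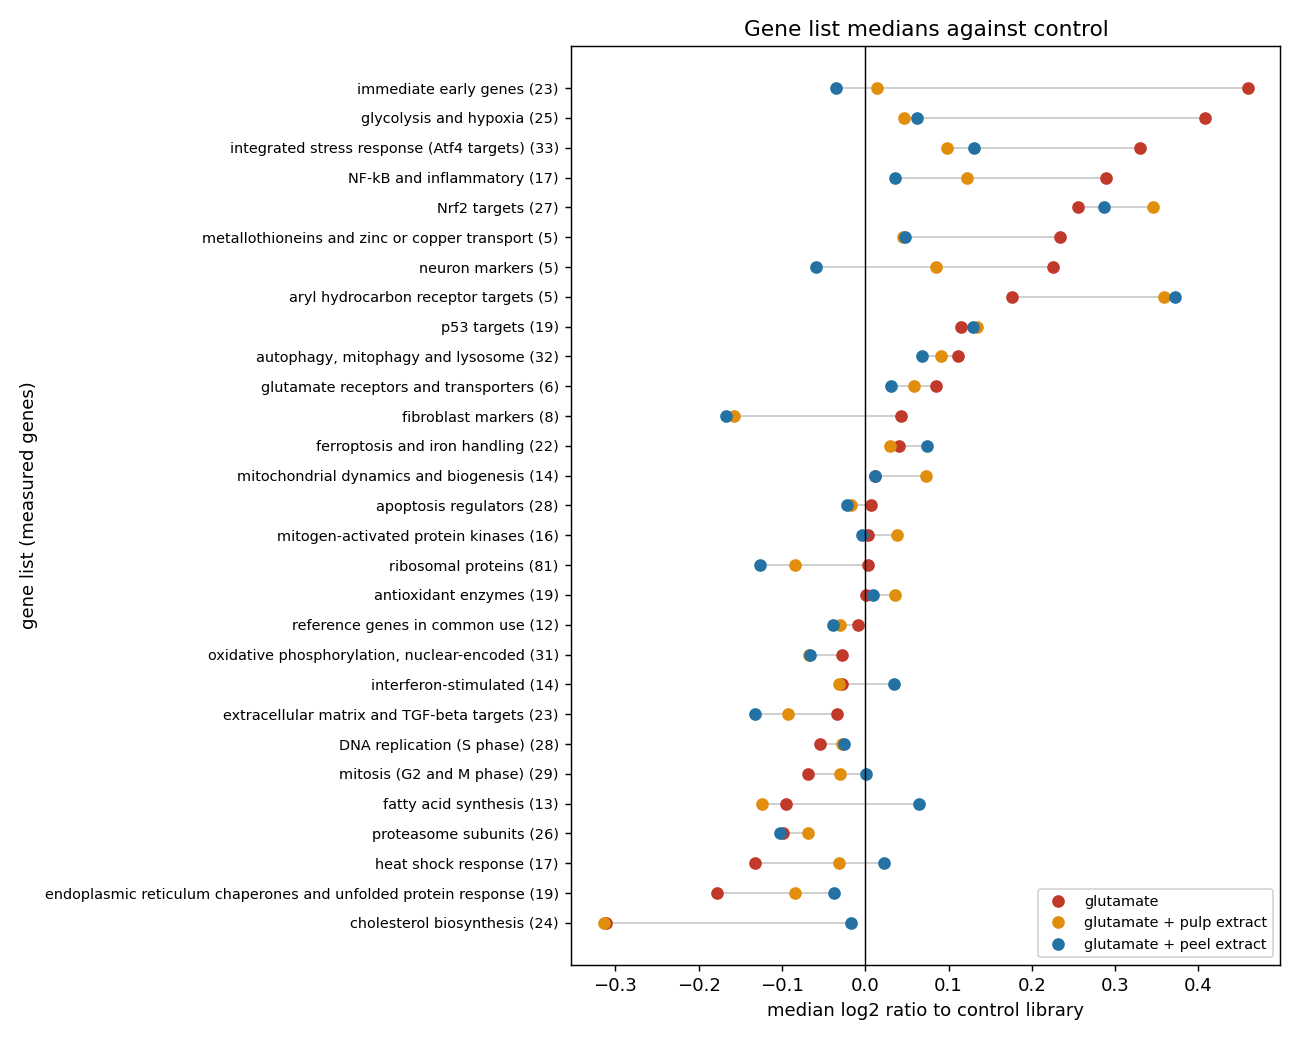
Median log2 ratio to the control library of each gene list with at least 5 measured genes, with 1 point per library and the number of measured genes in brackets. Immediate early, glycolysis and hypoxia, and Atf4 target medians were 0.46, 0.41 and 0.33 with glutamate alone and lay nearer 0 with both extracts, whereas the Nrf2 target median was 0.26, 0.35 and 0.29.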

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

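These contrasts were chosen after the data were seen, and the differences were not tested, since each group is a single library. Among 247 genes taken by the naming rule from the called genes, the genes always named and up to 4 members per list and comparison, 7 lay on opposite sides of the glutamate library with peel and with pulp extract, both beyond counting error. Scd2, a desaturase gene, had a log2 ratio to glutamate alone of 0.31 with peel and -0.11 with pulp extract. Further lipid enzymes were Elovl5, at 0.12 and -0.11, and Fads1, at 0.10 and -0.12, in the same order. The collagen cross-linking enzyme gene Lox was at 0.058 and -0.14. The ferritin genes went the other way, Fth1 at -0.16 and 0.08 and Ftl1 at -0.11 and 0.08, and the collagen gene Col1a1 was at -0.045 and 0.036. Scaling by FPKM totals moved the all-gene median of peel over glutamate from -0.0079 to 0.043, by more than the size of the Col1a1 ratio. Over 10394 measured genes, 44 lay on opposite sides and 1992 on the same side beyond counting error. The shared glutamate library favours the same side. Some of the 247 genes were taken for a large peel over pulp ratio, which favours opposite sides, so 7 of 247 cannot be set against 44 of 10394.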

How the results depend on the processing

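The use of recovered reads, under the rule laid out beforehand for counts, and the removal of genes listed at 0 were chosen after the data were seen. No paired analysis was possible because each group has 1 library. Under both scalings all 14 counts and shares stayed within the bounds set beforehand (1.5 times for counts, the 95% interval for shares), and all 116 list medians within 0.1 of the values reported. Both sets of factors lay between 0.97 and 1.02 relative to control, too near 1 to move a list median by 0.1, so that bound could hardly fail. The share intervals are wide for few genes, 3.19% to 65.1% for pulp extract and the 8 genes lower with glutamate. All-gene medians lay within 0.1 of 0 under every scaling. A reversal was not defined for counts and shares. List medians near 0 changed sign. Calls near the threshold ended with FPKM totals, among them those of Vegfa with glutamate, Tcim with pulp extract, and Egr1, Mt2 and Txnip with peel extract. The order of the extracts in the share of glutamate-higher genes called lower turned under several settings. The authors' calls are not used for peel against pulp, and a second unit was not run, since the tables hold 1. In this part a pair of counts gives genes higher then lower.

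With no minimum level, 13 genes were lower with glutamate than in control, 9 higher with pulp and 5 higher with peel extract, 12 lower with peel than pulp, and 2 higher with both extracts. With a minimum of 5 FPKM, which leaves fewer genes, the counts were 17 and 1 for glutamate, 1 and 7 for pulp, 7 lower for peel, 0 and 1 for peel against pulp, and 5 lower with both. The share of glutamate-lower genes higher with pulp extract was then 0 of 1 gene. A pseudocount of 1 FPKM gave 20 and 3 for glutamate, 12 lower for peel, and 4 and 4 for peel against pulp. An assumed coefficient of variation of 0.4 gave 11 and 2 for glutamate, 8 lower for pulp, 7 lower for peel, 4 higher for peel against pulp and 2 lower with both. The share of glutamate-higher genes lower with peel extract was then 18.2%, and 23.4% with divided glutamate reads. The authors' deposited table calls 3 higher with pulp and 4 with peel extract. Recovered reads, where scaling, pseudocount, minimum and call rule changed too, gave 103 and 17, 11 and 92, 16 and 108, and 30 and 28 in the 4 comparisons, with 2 higher and 43 lower with both extracts. They held 31 of 40, 25 of 27, 23 of 26 and 11 of 14 of the genes called from FPKM. Without genes listed at 0, 2 were higher with pulp and 3 with peel against pulp. At 5 FPKM, 2 list medians for glutamate moved, immediate early genes to 0.63 and extracellular matrix genes to -0.18. Except where fewer genes entered, the cause was not tested. Depth limits the genes of few reads, as the wide interval of Fgf21 (1.03 to 3.87) shows, and the single library per group limits all results.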

Other observations

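Extracellular matrix and TGF-beta targets went both ways with glutamate: of 23 measured genes 8 were higher and 11 lower beyond counting error, with a median of -0.03 above 1858 of 10000 random lists, which moved to -0.18 with a minimum of 5 FPKM. Thbs1, a matrix glycoprotein gene and target of TGF-beta, was at 13.9 FPKM with glutamate against 25.0 FPKM in control, a log2 ratio of -0.82 (-0.95 to -0.75). It was at 0.59 (0.50 to 0.71) with pulp and 0.54 (0.45 to 0.66) with peel extract over glutamate alone. Fn1, the fibronectin gene, was at 0.38 (0.36 to 0.41) with glutamate and at -0.32 and -0.30 with the extracts. Fibroblast markers, 8 measured, had medians of 0.04, -0.11 and -0.08 in these comparisons. Among them S100a4 was abundant in every library, at 5094 FPKM in control, 5240 with glutamate, 4683 with pulp and 4847 with peel extract. Neuron markers, 5 measured of 20, had medians of 0.23, -0.18 and -0.20. The neutral amino acid transporter gene Slc1a4 was at 0.53 (0.44 to 0.64) with glutamate, within 6 measured glutamate receptor and transporter genes of median 0.08. Of astrocyte and of microglia and macrophage markers 2 each were measured, with medians of 0.02 and 0.05 for glutamate. Of the 26 symbols listed for mitochondrially encoded genes, 0 occurred in the deposited data, so their level is unknown. Oligodendrocyte and endothelial markers, with 5 and 6 genes in the data, had 0 measured.

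Several lists lay inside the middle 95% of random lists for glutamate against control. Their medians were 0.04 for ferroptosis and iron handling (22 genes), 0.18 for aryl hydrocarbon receptor targets (5), -0.05 for S phase (28), -0.07 for mitosis (29) and -0.10 for fatty acid synthesis (13). They were -0.03 for nuclear-encoded oxidative phosphorylation (31), 0.01 for mitochondrial dynamics and biogenesis (14), -0.03 for interferon-stimulated genes (14), 0.01 for apoptosis regulators (28) and -0.01 for reference genes in common use (12). Antioxidant enzymes (19), mitogen-activated protein kinases (16) and ribosomal proteins (81) had medians above 6435, 5090 and 9644 of 10000 random lists. The medians of these 3 lists, of apoptosis regulators and of mitochondrial dynamics turned negative under other scalings. Among reference genes, Gapdh and Pgk1, both glycolytic, were at 0.35 (0.34 to 0.37) and 0.33 (0.30 to 0.35) with glutamate, and Actb at -0.21 (-0.23 to -0.19). Each extract put Gapdh lower, at -0.36 and -0.35.

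The tests of a shared or single glutamate library, of single cultures and of near-identical copies were chosen after their results were seen; those of scaling and gene length were not. Genes that differed with glutamate tended to differ the other way with each extract. Counting noise of the shared library is argued against, because the covariance nearest 0 over 100 divisions of the glutamate reads, for both extracts, was -0.0197. A deviation of the single glutamate culture or library that the treatment did not cause stays open and cannot be told apart from an effect of glutamate and the extracts, since each group has 1 library. Unchanged libraries with an assumed spread of 0.1 gave a covariance of -0.0244 beside the observed -0.0258 for pulp extract, but r of -0.50 beside -0.66, 2.51 genes called higher with glutamate beside 32, and 0.41 called lower with both extracts beside 9. These simulations gave all libraries the same spread, which puts r near -0.50 at any spread. They do not bound a deviation of the glutamate library alone, nor does the spread of 0.0400 estimated from 1 pair, peel and pulp.

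Cholesterol biosynthesis genes were higher with peel than with pulp extract, with a median of 0.26. The 3 other scalings tried do not account for this, since the smallest median under them was 0.27. Their factors differ little between the peel and pulp libraries, so they could not have removed it. Gene length does not account for it either, since the median lay at percentile 100 among random lists matched on level and length. A difference between the single cultures that the extracts did not cause could also give it. The list's median was -0.31 for pulp over control and -0.02 for peel over control, and with 1 culture per group this cannot be told apart from an effect of the extracts or their doses. That peel extract restores sterol synthesis genes may be taken as a hypothesis for replicated cultures at matched doses.

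Several called genes were listed at 0 in a library: 5 of 40 for glutamate against control, 8 of 27 for pulp, 2 of 26 for peel, and 5 of 14 for peel against pulp. A candidate explanation is that reads were divided differently between near-identical copies of a gene. In 12 of 14 cases with a copy in the tables (85.7%), the summed reads of the copies differed in the other direction, and family totals lay within counting error in 10 of 11 families and comparisons, the exception being Eif3j at 0.19 (0.09 to 0.30); for histones, with few reads, they still reached log2 ratios of 0.64 (Hist2h2aa) and -0.35 (Hist1h4) for pulp over glutamate, and -0.73 and -0.41 for peel over pulp. These cases come from 5 families and 8 genes picked after they were seen, and they recur across comparisons. The same exchange between Hist2h2aa1 and Hist2h2aa2 for glutamate against control entered as a case for each gene. All Entpd4 cases rest on the same glutamate reads, so the cases are not independent. A family dominated by 1 abundant copy can also give such a result with little division of reads. A further 6 cases had no copy by name, and no biological explanation was tested.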
